A study of Mus musculus with 1814 samples.

How the data were processed

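Single germinal center B cells of mice were index-sorted into plates and their RNA was sequenced by SmartSeq2, a full-length method without molecular identifiers. Each of the 1814 deposited samples was 1 well. The labels gave 5 sequencing experiments. In experiments 1 to 4 wells carried a Dec status, a time of 12, 30, 46 or 60 h and a zone. In experiment 5 they carried a genotype (WT, KO or TA) and a zone. The labels named no animal, so the experiment served as batch, and as replicate except in the comparison of zones. There each pair of zones of the same experiment and time served as replicate. No test counted cells as replicates, but the intervals of shares take cells as independent. For the 42 dark zone cells of experiment 1 the labels and a time column of the deposited cell table gave 30 h, while its column of groups gave 36 h, and 30 h was used. The plates of experiment 5 carried the name Ccnd3, but the labels did not state what was altered in KO and TA, nor what PB stands for in a set of wells of experiment 1.

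The deposited tables per plate and the deposited combined tables held expected counts per gene and well, estimated by the authors and not normalized. The submitters' notes named STAR 2.6, RSEM 1.3.1, Seurat 3.1.4 and mm10, without roles. The deposited cell tables also gave a score per cell for S phase and for G2M, the percent of reads in mitochondrial genes, the sort intensity of FUCCI, CXCR4, CD83, CD86 and forward scatter in arbitrary units, and other annotations by the authors (cell cycle phase as text and flags for each zone). The combined tables held 965 cells of experiments 1, 3 and 4 with 25125 genes, and 373 cells of experiment 5 with 15177 genes. For genes present in both, the combined table of experiments 1, 3 and 4 equalled the tables per plate, except for genes set to 0 in an experiment (1 in experiment 1, 2072 in experiment 3 and 2026 in experiment 4). Genes whose symbols end in Rik were absent from the combined table, and 1 gene starting with Gm remained, so that Gmnn, for example, was missing. Such genes took 4.57% of the reads of experiment 4 in the tables per plate.

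Experiment 2 (288 wells) was left out. Its 288 columns in the table per plate carried 96 names, so that no column matched 1 well, and its 255 columns in the combined table could not be assigned either. Zones could not be read from the labels for some wells, and these wells entered no zone comparison.

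For the comparisons of times and of zones, counts were summed over the kept Dec+ cells of each experiment, time and zone, leaving out the PB wells, and rounded. Sums of at least 10 cells were used (17 sums). Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3). The time course used 1 fit with the group (zone and time) and the experiment as block, 11661 genes and 7 residual degrees of freedom. The dark zone was set against the light zone in experiments 3 and 4 (7 pairs, 9302 genes). Experiment and time together were the block, since both zones came from the same harvest. The zone test thus took the 7 pairs as replicates, although they came from experiments 3 and 4 alone. Its p values do not rest on replication by experiment. Deviations of sums of the same experiment from their group means correlated across genes at r from 0.137 to 0.524 over 42 pairs of sums (median 0.330), and genes are not independent replicates. P values were adjusted by Benjamini-Hochberg over all genes of a comparison, and the threshold was 0.05. Gene lists (26 lists, 617 entries, fixed before the data were examined) were tested with camera at a preset inter-gene correlation of 0.01 on voom values, and again with an estimated correlation and with fry. Lists of fewer than 3 tested genes were not tested. Camera compares a list with the other genes tested, so lists said to rise or fall did so relative to those genes. Adjusted p values of lists are over the lists of a comparison.

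At 60 h the light zone had 1 sum, since that of experiment 4 held 5 cells. Its test took the spread from the other groups of the same fit and assumes that the lone sum varies like them. Comparisons in which every group had 1 experiment were given no test. These were Dec+ against Dec- cells, the genotypes, and PB wells against the other dark zone wells. Counts were summed per group and scaled to CPM by the total of the group, and ratios used a pseudocount of 1 CPM. For each list the median log2 ratio was taken over members at 20 CPM or more in either group. It was ranked among 10000 random lists matched on expression in 20 bins. Members of the random lists were drawn independently, so the percentiles ignore correlation between genes and are not p values. A percentile of 0 or 100 can rest on few wells or plates. T cell markers in KO against WT dark zone cells had the percentile 100 with plate medians from -1.62 to 6.35. The lowest and highest ratio over the plates are given for most lists described, but plates of an experiment are technical parts and not replicates. Intervals of CPM are 95% Poisson intervals and intervals of shares are 95% exact Clopper-Pearson intervals. The intervals of shares take cells as independent and cover counting error only. Those of CPM are too narrow even for counting error, since PCR reads without molecular identifiers are not independent molecules. Where a group had no count, the fold was computed against a floor of 3 counts over the group and is given as "at least". For such genes this is no lower bound on the change in RNA, since reads are not independent molecules and the cells are few. Fitted log2 ratios of such genes depend on the prior count and are not given.

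Genes were named by a rule fixed before the data were examined. In tested comparisons these were the 10 largest rises and 10 largest falls past the threshold with the same sign in every experiment or pair. In untested comparisons they were the 10 each way with at least 20 CPM in a group and a log2 ratio of size 1 or more in summed counts. The ratio also needed the same sign in every plate, but not that size. Genes were ranked by the plate with the smallest size. Up to 4 members per list described (2 where none passed), and a few fixed genes, among them Ccnd3, Ccnd2, Ccnd1, Myc, Cxcr4, Cd83 and Cd86, were added in each comparison. For 3 pairs of times and for secondary genotype contrasts only part of the named genes are printed, a choice made after their values were seen. Which results of the untested comparisons stand first was also chosen after their values were seen. Coordinates are from the GENCODE annotation of GRCm38 (mm10), in which all 39 genes looked up were found.

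Cell cycle phases were those of the authors. As alternatives they were called again from scores of the fixed lists, with all reads and with every cell thinned to 100000 reads. Wells with few B cell or many T cell genes were defined, after the data were seen, as those with fewer than 2 of 4 B cell genes, or with 5 or more T cell genes. Depth differed between experiments: the median count per cell was 417104 in experiment 1, 210349 in experiment 3, 292109 in experiment 4 and 155485 in experiment 5, and the totals per sum used ran from 2612729 to 135700242.

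Alternatives, fixed before the data were examined unless stated otherwise in the closing section, covered the block, size factors of DESeq2 in edgeR, the DESeq2 1.42.0 Wald test, filters on low counts, the minimum of 20 cells per sum, means of per-cell CPM with limma, all wells with at least 1000 genes, PB wells, each experiment or plate left out, CPM floors and pseudocounts. The procedures were tested on simulated data in which 200 genes were changed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.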

Results

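Germinal center B cells cycle between a light zone, where they receive help from T cells, and a dark zone, where they divide. The series measured RNA of single cells from both zones at 12, 30, 46 and 60 h, and of single cells of the genotypes WT, KO and TA. It covered 1814 wells, and the kept cells that could be used numbered 353 in experiment 3, 324 in experiment 4 and 373 in experiment 5, besides those of experiment 1. Experiment 1 held 166 Dec+ and 80 Dec- light zone cells of 12 h and 42 Dec+ dark zone cells of 30 h. Experiment 3 held 43, 62, 73 and 69 dark zone cells and 46, 22, 11 and 21 light zone cells at 12, 30, 46 and 60 h. Experiment 4 held 55, 67, 54 and 78 dark zone cells and 26, 22, 17 and 5 light zone cells at these times. Experiment 5 held 82 WT, 62 KO and 101 TA cells of the dark zone, and 41, 61 and 22 of the light zone. Counts per kept cell ran from 100908 to 5828103 in experiment 1, from 2156 to 443196 in experiment 3, from 10662 to 557857 in experiment 4 and from 1300 to 290570 in experiment 5. The median percent of mitochondrial reads was 11.2 in experiment 1, 1.42 in experiment 3, 3.99 in experiment 4 and 7.44 in experiment 5.

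The comparison of zones asked which transcripts differ between dark and light zone cells of the same harvest. Among genes higher in the dark zone were Hmces and Neil1, with known roles in DNA repair, while the list of hypermutation and repair genes did not pass in camera (median log2 ratio 0.29). Hmces, a sensor of abasic sites (chromosome 6, 87913935 to 87936629), rose by a log2 ratio of 1.77 ± 0.17 (SE, edgeR adjusted p = 0.00246), from 353 ± 200 CPM to 1080 ± 403 CPM (SD, n = 7 sums). Neil1, a DNA glycosylase, rose by 1.16 ± 0.13 (adjusted p = 0.00494). Light zone cells had more RNA of activation genes: Cd83 (chromosome 13, 43784775 to 43803132) had 3121 ± 1292 CPM there and 932 ± 590 CPM in the dark zone (log2 ratio -1.80 ± 0.26, edgeR adjusted p = 0.0126). The zone labels go with staining for CXCR4 and CD83, so the transcripts Cd83 and Cxcr4 are not independent evidence of the zones.

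In all, 19 genes were higher and 15 lower in the dark zone among 9302 tested with edgeR, and 18 and 14 of these had the same sign in all 7 pairs. The largest rises and falls named next are among these 18 and 14 genes. Besides those above, the largest rises were Rgcc (2.22), Mtf2 (1.81), Otub2 (1.75), Ifi209 (1.48), Anxa2 (1.37), Gcsam (1.20), Cdc20 (1.19) and Cenpa (1.14) on the log2 scale. The largest falls were Cd40, the receptor for T cell help (-1.75), Fcer2a (-1.60), Nfkb2 (-1.49), Bcl2a1b (-1.41), Nfkbia (-1.40), Gimap4 (-1.34), Cd86 (-1.29), Ifi30 (-1.11) and Noc4l (-1.11). Adjusted p values of these genes lay between 0.00716 and 0.0455 (edgeR). Ccnd3, which encodes cyclin D3 (chromosome 17, 47505051 to 47599691), had 773 ± 154 CPM in the dark zone and 632 ± 194 CPM in the light zone (n = 7) and did not pass (log2 ratio 0.32 ± 0.13, above 0 in 7 of 7 pairs, edgeR adjusted p = 0.433). Nor did Myc (-1.44 ± 0.41, adjusted p = 0.213), Cxcr4 (3.22 ± 0.95, adjusted p = 0.238) or Ccnd2 (-3.46 ± 1.64, adjusted p = 0.555) in edgeR.

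**Figure D1:**
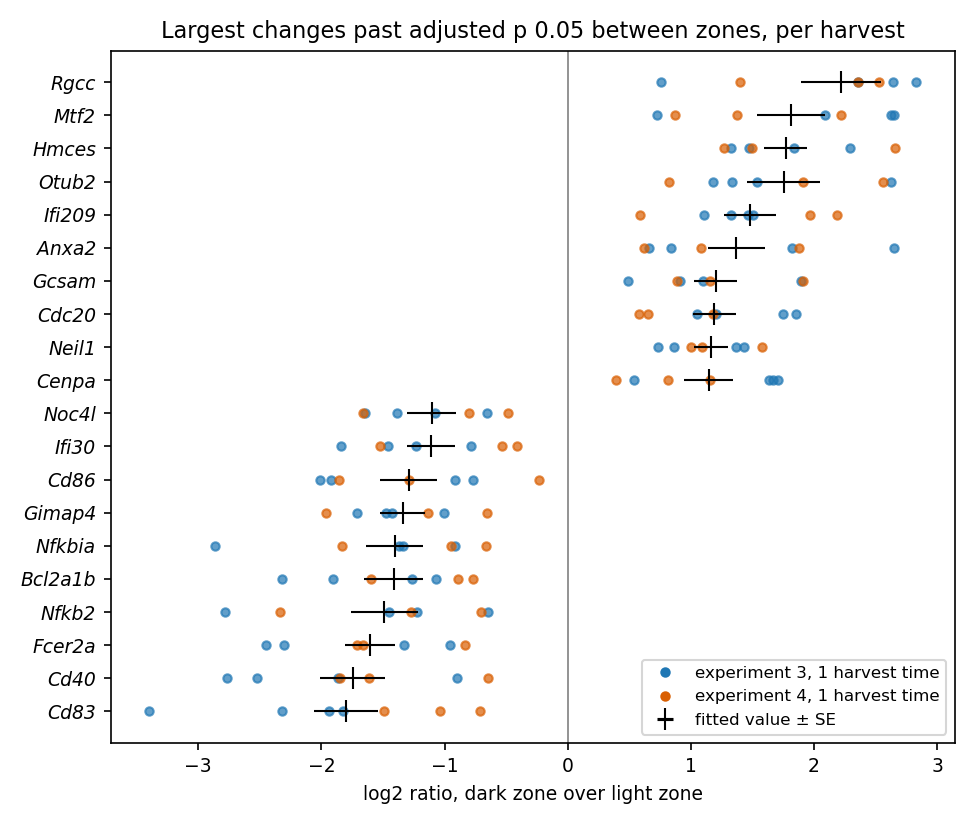
Log2 ratio of dark over light zone for the 10 largest rises and 10 largest falls past the threshold with the same sign in all 7 pairs. Each harvest has 1 point (4 of experiment 3 and 3 of experiment 4, by color), and a black mark gives the fitted value ± SE. Hmces was fitted at 1.77 and Cd83 at -1.80, and the points of each gene lay on 1 side of 0, as the choice of genes required.

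Of 23 gene lists, 3 rose and 11 fell in the dark zone with camera at the preset correlation, and 1 and 6 of these calls were kept with an estimated correlation. The list of MYC-dependent growth and ribosome biogenesis genes fell, with a median log2 ratio of -0.67 and no median above 0 in the 7 pairs. Of its 38 members 1 fell, and 29 fell adjusted over the list alone (adjusted p = 0.0202 with an estimated correlation). The member past the threshold was Nop16 (-1.06). The light zone list fell (median -0.95), with 8 of 29 members falling and 16 adjusted over the list alone (adjusted p = 0.0189 with an estimated correlation). Its largest fall was Il4i1 (-2.45 ± 0.39, lower in 6 of 7 pairs, edgeR adjusted p = 0.0201). The dark zone list rose (median 0.42), with 2 of 19 members rising, Gcsam among them, and 5 adjusted over the list alone (adjusted p = 0.0202 with an estimated correlation). Genes of NF-kB and CD40 signaling fell (median -0.91), with 1 of 19 members falling, Junb (-0.97), and 3 adjusted over the list alone (adjusted p = 0.0202 with an estimated correlation). Genes of MHC class II presentation fell (median -0.27), with 0 of 18 members past the threshold over all genes in edgeR and 8 adjusted over the list alone (adjusted p = 0.0202 with an estimated correlation). The lists of the unfolded protein response (median -0.25) and of memory-like genes (median -0.32) fell as well, with adjusted p = 0.0423 and adjusted p = 0.0451 with an estimated correlation.

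Mitotic genes rose in the dark zone (median 0.48), with 4 of 66 members rising, Cdc20, Cenpa (1.14), Ccnb2 (1.11) and Cenpe (1.07), and 14 adjusted over the list alone. This list call was lost with the other correlation (adjusted p = 0.0677 with an estimated correlation). Also lost were glycolysis (median -0.33, adjusted p = 0.0663 with an estimated correlation), mTORC1 targets (-0.15, adjusted p = 0.186 with an estimated correlation) and apoptosis regulators (-0.09, adjusted p = 0.208 with an estimated correlation). The same held for interferon response (0.89, adjusted p = 0.401 with an estimated correlation), dissociation stress (-0.12, adjusted p = 0.186 with an estimated correlation) and ribosomal proteins (-0.04, adjusted p = 0.497 with an estimated correlation). G1/S replication genes had a median of 0.06 and did not pass. The median over all genes was 0.20, and it was 0.07 among genes with a mean of 20 CPM or more. Tests of single genes set each ratio against 0, while camera set a list against the other genes. A list with a median near 0, such as ribosomal proteins, could therefore be called lower without a fall in its RNA. Without the block for experiment and time the count of genes dropped to 1, without experiment 3 it was 0 in edgeR and without experiment 4 it was 3. It was 3 with sums of at least 20 cells, 76 without the 97 cells that the authors marked for both zones, and 472 in the DESeq2 test.

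The dark zone time course asked what changes in Dec+ dark zone cells from 12 to 60 h. Ccnd3 RNA was 685 ± 44.6 CPM at 12 h, 810 ± 298 CPM at 30 h, 824 ± 167 CPM at 46 h and 779 ± 9.64 CPM at 60 h (SD, n = 2 experiments). These means are over experiments 3 and 4, which hold all times. The 30 h sum of experiment 1, which holds no dark zone sum of 12 h and enters the fit with experiment as block, had 1547 CPM of Ccnd3, 15.2 CPM of Myc and 143 CPM of Cd83. Myc had 74.5 ± 56.6, 52.6 ± 10.6, 35.1 ± 0.521 and 19.0 ± 3.89 CPM, and its log2 ratio of 60 over 12 h was -1.98 ± 0.68. Cd83 had 1556 ± 856, 928 ± 0.514, 416 ± 17.6 and 627 ± 141 CPM. None of these passed, and no gene passed in any of the 6 pairs of times with edgeR. For 30, 46 and 60 h against 12 h edgeR gave 0 genes, with 269, 511 and 196 of 11661 at an unadjusted p under 0.05, while DESeq2 gave 91, 136 and 98. For 46 against 30 h, 60 against 30 h and 60 against 46 h edgeR gave 0, with 183, 107 and 202 at an unadjusted p under 0.05, and DESeq2 gave 41, 24 and 67. On simulated data edgeR recovered 0, 7, 13 and 25 of 50 genes changed 2-fold, 4-fold, 8-fold and 16-fold at this size. Small changes were thus not detectable and large ones were often missed, so the 0 genes do not exclude large changes.

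**Figure D2:**
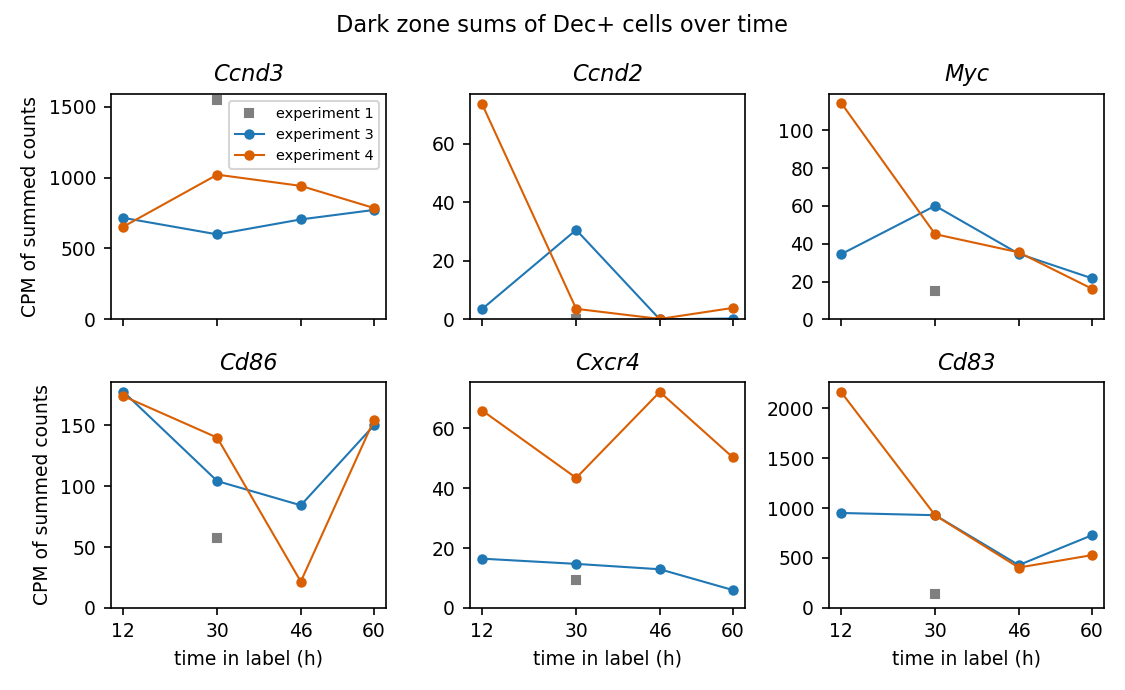
CPM of Ccnd3, Ccnd2, Myc, Cd86, Cxcr4 and Cd83 per sum of dark zone Dec+ cells against time in h, with lines for experiments 3 and 4 and a square for experiment 1. Over experiments 3 and 4 Ccnd3 lay at a mean of 685 CPM at 12 h and 779 CPM at 60 h, and Myc at 74.5 and 19.0 CPM.

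As groups, cell cycle genes rose from 12 h on in the camera test. At 30 h the G1/S list had a median log2 ratio of 0.35 over 12 h, with 43 of 46 members above 0, and the mitotic list had 0.63, with 60 of 66 above 0 (adjusted p = 0.508 and adjusted p = 0.639 with an estimated correlation). At 46 h these medians were 0.21 and 0.59 (adjusted p = 0.549 for both with an estimated correlation), and at 60 h they were 0.30 and 0.55 (adjusted p = 0.553 and adjusted p = 0.609 with an estimated correlation). Experiments differed for mitotic genes, with medians of -0.0069 and 1.17 at 46 h and 0.04 and 0.99 at 60 h. Light zone genes fell, with medians of -0.72, -0.88 and -0.56 at 30, 46 and 60 h against 12 h (adjusted p = 0.464, adjusted p = 0.249 and adjusted p = 0.394 with an estimated correlation). Adjusted over the list alone, 5 of 30 light zone members fell at 46 h. Ribosomal protein genes rose, with medians of 0.22, 0.77 and 0.18 (adjusted p = 0.662, adjusted p = 0.249 and adjusted p = 0.627 with an estimated correlation). At 46 h all 36 were above 0 and 28 rose adjusted over the list alone. Growth genes dependent on MYC rose at 30 h (0.29) and fell at 60 h (-0.11) against 12 h (adjusted p = 0.662 and adjusted p = 0.595 with an estimated correlation), with medians of -0.30 and 0.12 in the experiments at 60 h.

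At 30 against 12 h mTORC1 targets (0.42) and glycolysis (0.38) also rose, and NF-kB genes (-0.70), MHC class II genes (-0.23) and myeloid markers (-0.74 and -0.60 in the experiments) fell. Their estimates lay between adjusted p = 0.464 and adjusted p = 0.662 with an estimated correlation. At 46 against 12 h oxidative phosphorylation (0.55), glycolysis (0.43) and mitochondrial transcripts (0.28) rose, and FOXO1 targets (-0.82), unfolded protein response (-0.44), B cell identity (-0.32), plasma cell (-0.28), NF-kB (-0.33) and MHC class II genes (-0.11) fell. These lay between adjusted p = 0.249 and adjusted p = 0.574 with an estimated correlation, and MHC class II medians were -0.48 and 0.18 in the experiments. Genes that differ by the sex of the mouse fell too, with a median between -1.39 and 0 over the experiments (adjusted p = 0.301 with an estimated correlation). At 60 against 12 h unfolded protein response (-0.30) and MHC class II genes (-0.25) fell (adjusted p = 0.355 and adjusted p = 0.595 with an estimated correlation). T cell markers rose at 60 h, with medians of 0.47 and 2.08 in the experiments (adjusted p = 0.355 with an estimated correlation). In the same dark zone groups 4 of 69 cells of experiment 3 and 10 of 78 of experiment 4 had 5 or more T cell genes, and no cell of 12 h in either had. All 4 and 10 of these wells also had at least 2 of 4 B cell genes. Between the later times, MYC-dependent growth genes fell from 30 to 60 h (-0.52) and from 46 to 60 h (-0.41) with adjusted p = 0.235 and adjusted p = 0.369 with an estimated correlation. Ribosomal protein genes rose from 30 to 46 h (0.52) and fell from 46 to 60 h (-0.59) with adjusted p = 0.316 and adjusted p = 0.298 with an estimated correlation. No list of the time courses was kept with an estimated correlation or with fry.

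The light zone time course asked the same of light zone cells. At 46 h the histone gene H2afx had 611 ± 231 CPM against 192 ± 4.45 CPM at 12 h (n = 2 experiments) and rose by 1.70 ± 0.25 on the log2 scale (edgeR adjusted p = 0.0194). Selenop (4.06 ± 0.76), Bicra (2.85 ± 0.56) and Acap1 (1.73 ± 0.34) rose as well (edgeR adjusted p = 0.0329, adjusted p = 0.0395 and adjusted p = 0.0416). Another 48 genes fell, and the 10 largest falls were genes with no count at 46 h. These were Zfp51 (at least 131-fold lower), Phc3 (at least 94.8-fold), Klf10 (at least 91.6-fold), Mlst8 (at least 90.1-fold), Rnf170 (at least 88.9-fold), Zfp780b (at least 80.8-fold), Zyg11b (at least 69.0-fold), Cpt2 (at least 63.1-fold), Hsd17b4 (at least 58.6-fold) and Alg11 (at least 48.7-fold). Ccnd3 had 601 ± 110 CPM at 46 h and 478 ± 104 CPM at 12 h and did not pass (0.52 ± 0.30, edgeR adjusted p = 0.543). The sums of 46 h held 11 and 17 cells, so a gene read in few cells can have no count by sampling. Folds given as "at least", here and at 60 h, are therefore not lower bounds on the change. The median log2 ratio of all genes was -0.30. Without experiments 1, 3 and 4 in turn, 15, 20 and 42 genes passed, of which 14, 1 and 3 were among the 52, and DESeq2 gave 1054.

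At 60 against 12 h, the 60 h group was 1 sum of 21 cells of experiment 3, assumed to vary like the sums of other groups. On that assumption Tuba1a (2.12 ± 0.31) and H2afx (1.93 ± 0.31) rose, and 12 genes fell in edgeR. Genes with no count at 60 h were Ighe (at least 101-fold lower), Otud6b (at least 83.7-fold), Dhx38 (at least 77.9-fold), Polr3e (at least 74.5-fold), Tmem175 (at least 62.4-fold), Abt1 (at least 49.5-fold) and Akr7a5 (at least 33.1-fold). The median over all genes was -0.27, and without experiment 1 or 4 no gene passed in edgeR. At 30 against 12 h edgeR gave 0 genes, with 405 at an unadjusted p under 0.05 and 118 by DESeq2. Among lists, mitotic genes rose at 30 h (0.15), 46 h (0.53) and 60 h (0.85), with adjusted p = 0.918, adjusted p = 0.661 and adjusted p = 0.731 with an estimated correlation. The experiment medians at 30 h were -0.33 and 0.43. At 46 h ribosomal proteins (0.42), oxidative phosphorylation (0.33), G1/S genes (0.06) and mitochondrial transcripts (0.04) were called higher than the other genes. Called lower were mTORC1 targets (-0.63) and memory-like genes (-1.56 and -0.24 in the experiments). Each of these lists had adjusted p = 0.661 with an estimated correlation. The median over all genes was -0.30 there, and -0.02 among genes with a mean of 20 CPM or more. For G1/S genes and mitochondrial transcripts the calls therefore show no rise with time. In the experiments the list medians were -0.28 and 0.89 for ribosomal proteins, -0.29 and 0.80 for oxidative phosphorylation and -0.25 and 0.36 for mitochondrial transcripts. At 60 h G1/S genes (0.54) and T cell markers rose (adjusted p = 0.715 and adjusted p = 0.731 with an estimated correlation). The difference between zones in the change from 12 to 30 h had 0 genes past the threshold in edgeR, with 323 at an unadjusted p under 0.05 and 153 by DESeq2. For Ccnd3 this difference was -0.44 ± 0.45. Its fit was that of the time course, with experiment alone as block, so the pairing of zones by harvest was not used.

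Dark zone shares were counted among cells with a zone. In experiment 3 they were 48.3% (37.6 to 59.2) at 12 h, 73.8% (63.1 to 82.8) at 30 h, 86.9% (77.8 to 93.3) at 46 h and 76.7% (66.6 to 84.9) at 60 h. In experiment 4 they were 67.9% (56.6 to 77.8), 75.3% (65.0 to 83.8), 76.1% (64.5 to 85.4) and 94.0% (86.5 to 98.0). In experiment 5 the share was 66.7% (57.6 to 74.9) in WT, 50.4% (41.2 to 59.5) in KO and 82.1% (74.2 to 88.4) in TA. Over the 8 shares of experiments 3 and 4 the mean slope was 0.562 points per h (exact permutation of times within experiments, two-sided p = 0.0208, 12 of 576 arrangements as large), a test chosen after the values were seen. With all wells as denominator the slope was 0.445 points per h and did not pass (exact permutation p = 0.0781), and in experiment 4 the share was then 57.3% at 12 h and 56.2% at 46 h. The genotypes had 1 experiment, so no exact test of theirs could reach the threshold.

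**Figure D3:**
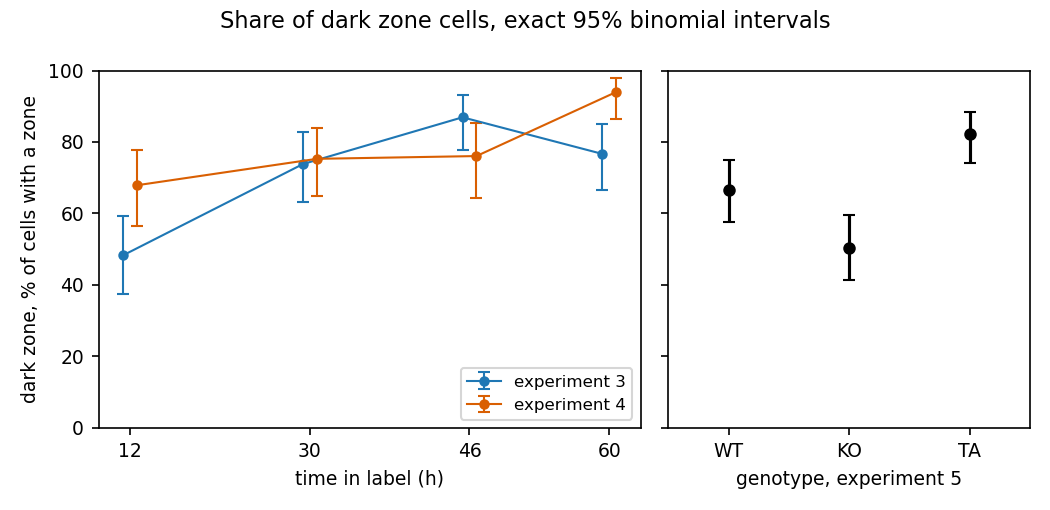
Percent of cells in the dark zone, with exact 95% intervals, by time in experiments 3 and 4 and by genotype in experiment 5. The share was 48.3% and 67.9% at 12 h and 76.7% and 94.0% at 60 h, and it was 50.4% in KO, 66.7% in WT and 82.1% in TA.

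By the authors' phases, G1 cells made up 60.5% (44.4 to 75.02), 40.3% (28.1 to 53.5), 27.4% (17.6 to 39.1) and 26.1% (16.3 to 38.1) of dark zone cells of experiment 3 at 12, 30, 46 and 60 h. In experiment 4 they made up 41.8% (28.7 to 55.9), 22.4% (13.1 to 34.2), 24.1% (13.5 to 37.6) and 32.1% (21.9 to 43.6). Phase calls rest on transcripts alone.

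The genotype comparison set KO and TA against WT cells of experiment 5, by zone. Ccnd3 RNA in the dark zone was 477 CPM (464 to 490) in WT, 89.3 CPM (83.3 to 95.5) in KO and 287 CPM (280 to 295) in TA. The log2 ratio of KO over WT was -2.40 (-2.99 to -1.44 over 4 plates) and that of TA over WT was -0.73 (-0.98 to -0.52). In the light zone these ratios were -2.14 and -1.55, and that of KO was -3.59 without the 18.0% of KO cells there that lacked B cell genes or had many T cell genes. Genes of G1/S and replication were lower in KO dark zone cells than in WT, with a median log2 ratio of -1.69 (-2.55 to -1.12 over plates), 1 of 45 members above 0 and the percentile 0 of random lists. Among them were Cdc6 (-4.69), which loads the replicative helicase, Ccne2 (-3.90), Mcm10 (-3.70) and Gins1 (-3.50). In TA dark zone cells the same list was higher than in WT (0.65, 0.58 to 1.09 over plates, 42 of 46 above 0, percentile 100), with Uhrf1 (2.04), Cdc6 (1.78), Chaf1b (1.41) and Rfc4 (1.31).

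Mitotic genes followed, with a median of -0.85 in KO (3 of 61 above 0, percentile 0) and 0.35 in TA (50 of 62 above 0, percentile 100) against WT in the dark zone. Members were Anln (-2.04), Cdca8 (-1.66), Bub1 (-1.63) and Ctcf (-1.54) in KO, and Tacc3 (1.51) and Top2a (1.06) in TA. Over plates these medians ran from -1.57 to 0.13 in KO and from -0.44 to 1.19 in TA. Genes of hypermutation and repair were lower in KO (-1.11, -1.998 to -0.67 over plates, 1 of 16 above 0, percentile 0). Among them were Exo1 (-3.19), Rpa2 (-2.37), Apex1 (-2.01) and Msh6 (-1.74). This list shares Msh6 with the G1/S list, and KO had a smaller share of S phase cells, as given below. The difference in repair genes was not tested apart from phase. MYC-dependent growth genes were lower in KO as well (-0.61, -1.13 to 0.02 over plates, 5 of 35 above 0, percentile 0.69), with Nop2 (-1.83), Gnl3 (-1.63), Bop1 (-1.54) and Nop58 (-1.39). Ccnd2, which encodes another D-type cyclin, had 76.5 CPM (71.1 to 82.4) in KO, 8.78 CPM (7.16 to 10.7) in WT and 1.38 CPM (0.912 to 2.05) in TA dark zone cells, with reads in 17.7%, 4.88% and 0.99% of cells. Its log2 ratio of KO over WT was 2.99, and it ran from 0.79 to 7.18 over plates.

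Interferon response genes were higher in both KO (1.85, 13 of 14 above 0, percentile 100) and TA (1.17, 14 of 14 above 0, percentile 100) than in WT dark zone cells. Over plates these medians ran from -0.14 to 3.28 in KO and from 0.48 to 2.30 in TA. Examples were Irf1 (2.84), Oas1a (2.44) and Ifi27l2a (1.41) in KO and Ifi213 (3.18), Usp18 (2.39) and Irf1 (2.24) in TA. In KO, ribosomal proteins (0.68, 35 of 36 above 0) and mitochondrial transcripts (0.49, 10 of 12) were higher than in WT, with ranges over plates of 0.47 to 0.71 and 0.25 to 0.70. NF-kB genes (1.39, 11 of 13) and light zone genes (0.43, 18 of 26) were higher in summed counts, but ran from -0.18 to 1.62 and from -0.73 to 1.13 over plates. Examples were Rplp1 (1.14), Rpl23 (1.06), Junb (1.45), Cd52 (1.01) and mt-Co1 (0.77). In KO plasma cell genes had a median of 0.34 (0.10 to 0.96 over plates, 13 of 20 above 0), with Derl3 (3.27), Ell2 (1.20), Jchain (1.16) and Ssr4 (1.04). In TA, MHC class II genes (-0.35, 4 of 18 above 0) and ribosomal proteins (-0.22, 2 of 36) were lower than in WT, with ranges over plates of -0.56 to -0.03 and -0.66 to -0.0064. Light zone genes (-0.33, 6 of 23) ran from -0.85 to 0.22 over plates. FOXO1 targets (-0.63, 0 of 8, percentile 2.3) ran from -0.68 to 0.097, and without wells with few B cell or many T cell genes their median was -0.18 over 5 genes (percentile 18.4). H2-Ab1 (-0.61) and Cd74 (-0.37) were members of the first. T cell markers were higher in KO (3.97, -1.62 to 6.35 over plates), where 8.06% of dark zone and 18.0% of light zone cells lacked B cell genes or had many T cell genes, against 1.22% of WT and 0.99% of TA dark zone cells.

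**Figure D4:**
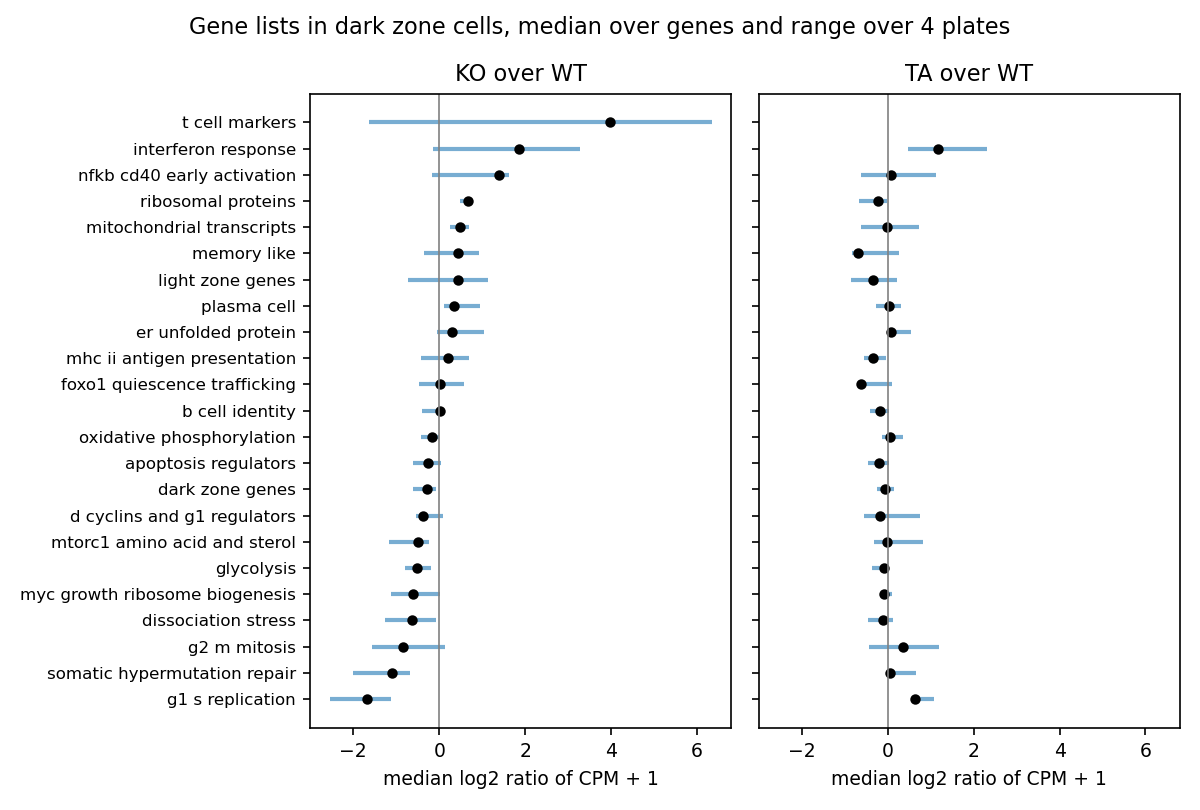
Median log2 ratio of gene lists in dark zone cells, KO over WT and TA over WT, with points for the cells of all plates and lines from the lowest to the highest of 4 plates. G1/S genes lay at -1.69 in KO and 0.65 in TA, and mitotic genes at -0.85 and 0.35.

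By the rule on single genes, the largest differences from WT of KO dark zone cells were higher for Zfp951 (5.97), Gvin1 (4.64), Il6ra (4.44), Nucb2 (4.28), Cers6 (4.13), Pls1 (4.05), Pex3 (3.87), Zfp810 (3.61), Nbdy (3.57) and Xpnpep3 (3.29). Lower in KO were Phtf1os (-5.50), Gart (-4.61), Palb2 (-3.89), Mid1 (-3.88) and Sap30, with 0.215 CPM (0.026 to 0.775) against 43.5 CPM, and Ptk2, Taf9b, L3mbtl3, Cyp39a1 and Snx16 had no count in KO. In TA the higher genes were Nanos1, with no count in WT, Tgtp2, with 54.2 CPM against 0.172 CPM (0.0208 to 0.622), Oasl2, with 41.2 CPM against 0.258 CPM (0.0532 to 0.754), Praf2, with no count in WT, Pank3 (4.13), Mapkapk2 (4.04), Brca2 (3.27), Ppp3cb (2.88), Zfyve1 (2.48) and Ampd2 (2.13). Lower were L3mbtl3, with 0.161 CPM (0.0332 to 0.471) against 31.3 CPM, Mterf1b (-4.51), Amd2 (-4.16), Atp11a (-3.27), Ddhd1 (-3.11), Dock9 (-3.00), Cdk5rap1 (-2.81), Mrps6 (-2.75), Zfp746 (-2.64) and Cd200 (-2.63). On simulated data of KO against WT 181 genes without a change, of 6505 expressed, passed the rule. It asks for a log2 ratio of size 1 or more in summed counts and the same sign in every plate. How many reach larger sizes was not counted.

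G1 cells made up 46.3% (35.3 to 57.7) of WT, 77.4% (65.0 to 87.1) of KO and 22.8% (15.02 to 32.2) of TA dark zone cells. S phase cells made up 24.4% (15.6 to 35.1), 3.23% (0.393 to 11.2) and 45.5% (35.6 to 55.8), and G2M cells 29.3% (19.7 to 40.4), 19.4% (10.4 to 31.4) and 31.7% (22.8 to 41.7). In the light zone G1 cells made up 36.6% (22.1 to 53.1) of WT, 73.8% (60.9 to 84.2) of KO and 54.5% (32.2 to 75.6) of TA. There G1/S genes had medians of -1.34 in KO and -0.40 in TA against WT, and mitotic genes -0.85 and -0.39. TA against KO gave G1/S medians of 2.47 in the dark zone (46 of 46 above 0) and 1.23 in the light zone, and mitotic medians of 1.07 and 0.64. The direction of TA against WT thus differed between zones, a difference that was not tested. With 22 TA cells in the light zone, the G1/S median was 0.07 without plate 3 and the mitotic median 0.17 without plate 2, and the mitotic median of TA over KO was -0.15 without plate 4. Genotype and animal cannot be separated in 1 experiment.

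**Figure D5:**
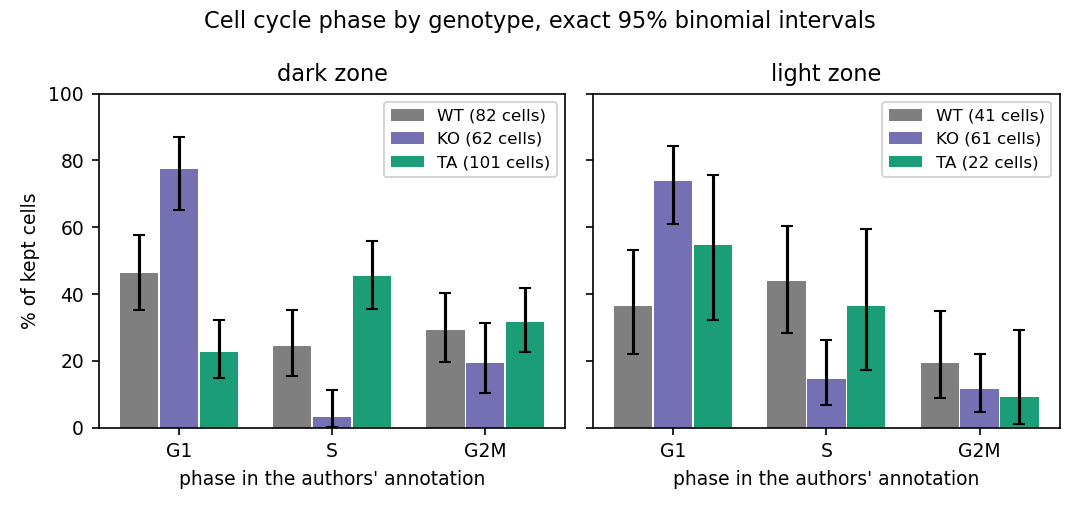
Percent of cells in G1, S and G2M by genotype and zone in experiment 5, with exact 95% intervals. In the dark zone G1 cells made up 46.3% of WT, 77.4% of KO and 22.8% of TA.

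The comparison of Dec+ with Dec- cells used light zone cells of 12 h of experiment 1. Myc RNA (chromosome 15, 61985391 to 61990374) was 200 CPM (197 to 202) in Dec+ and 74.3 CPM (71.9 to 76.7) in Dec- cells, with a log2 ratio of 1.41 (0.78 to 1.93 over 3 plates). MYC-dependent growth genes were higher in Dec+ (median 1.18, 1.00 to 1.47 over plates, 37 of 38 above 0, percentile 100). Examples were Nop16 (2.44), Srm (2.31), Nolc1 (2.24) and Hspd1 (2.01). Unfolded protein response (0.89, 12 of 15 above 0), glycolysis (0.65, 12 of 13) and G1/S genes (0.31, 31 of 45) were also higher, with ranges over plates of 0.63 to 0.98, 0.49 to 0.82 and 0.12 to 0.60. NF-kB genes (0.88, 11 of 13) ran from -0.43 to 1.31. Among their members were Sdf2l1 (1.45), Pdia4 (1.25), Batf (1.62), Nfkb1 (1.47), Slc2a1 (2.13), Tpi1 (1.16), Rfc4 (1.40) and Lig1 (1.22). B cell identity genes were lower (-0.44, -0.66 to -0.31 over plates, 2 of 14 above 0, percentile 1.17), with Cd79a at -1.34. Ccnd3 had 575 CPM in Dec+ and 597 CPM in Dec- (log2 ratio -0.06), and Ccnd2 had 79.5 and 14.9 CPM (2.34). Mitotic genes had a median of -0.18 that ran from -0.82 to 0.60 over plates. Genes that differ by the sex of the mouse had a median of -1.06 (0 of 3 above 0, -1.75 to -0.50 over plates, percentile 5.04). The labels name no animal, so Dec status and animal cannot be separated either.

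Single genes higher in Dec+ were Fastkd3 (4.83), Zfp53 (4.67), Gbp2, with no count in Dec-, Prps1 (4.34), Sec62 (4.25), Fscn1 (4.15), Shmt1 (4.14), Zfp951 (3.95), Nle1 (3.85) and Ptprv (3.49). Lower were Ackr2 (-4.93), Renbp (-4.66), Cd59a (-3.65), Nhlrc3 (-3.30), Klf7 (-3.26), Cyp2r1 (-3.11), Bhlhe40 (-2.94), Herc6 (-2.74), Ric8b (-2.58) and Trim56 (-2.56). G1 cells made up 42.2% (34.6 to 50.1) of Dec+ and 58.8% (47.2 to 69.6) of Dec- cells. Dissociation stress genes were higher in Dec+ (0.76, 7 of 10 above 0), but -0.11 with the mean of per-cell CPM. On simulated data 294 genes without a change, of 6019 expressed, passed the rule. It asks for a log2 ratio of size 1 or more in summed counts and the same sign in every plate.

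The PB wells of 30 h were set against the other dark zone wells of that plate, a comparison whose purpose the labels do not give. The combined table held no PB wells, so all wells with at least 1000 genes were used here. These were 40 PB and 47 other wells, among them wells that the authors had not kept. Ccnd3 was lower in PB wells, with 804 CPM (793 to 815) against 1534 CPM (1518 to 1551). So were G1/S genes (-0.93, 4 of 44 above 0, percentile 0), among them Usp1 (-2.21), Mcm2 (-2.05), Msh6 (-1.96) and Mcm10 (-1.95), and mitotic genes (-0.72, 3 of 63, percentile 0), among them Aurka (-2.49), Ndc80 (-2.11), Plk1 (-1.71) and Hmmr (-1.63). Unfolded protein response (-0.98, 4 of 15) and repair genes (-0.85, 1 of 16) were lower, with Hspa5 (-1.90), Manf (-1.86), Xrcc6 (-2.17, but 0.10 with the mean of per-cell CPM) and Apex1 (-1.98). MHC class II genes were higher (0.67, 16 of 18 above 0), with H2-Oa at 1.96. NF-kB (1.59) and memory-like genes (1.92) were higher in summed counts but had medians of -0.69 and -0.12 with the mean of per-cell CPM. The largest single differences rested on few wells: Kif3c was seen in 12.5% and Ptprz1 in 2.5% of PB wells, and Olfr1384 and Cercam in 2.13% of the others. Both sets came from 1 plate, so no range over plates can be given.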

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

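Tests chosen only after the result was seen were the one of genes at low counts, both tests over other splits of the sums, the definition of wells with few B cell or many T cell genes, and the alternative without cells marked for both zones.

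The difference between zones in the change from 12 to 30 h was tested as an interaction, with experiment alone as block. With camera at the preset correlation 5 gene lists passed. For MYC-dependent growth genes the change in the dark zone exceeded that in the light zone by a median log2 value of 0.75, with 32 of 38 members above 0 (camera adjusted p = 0.00187, and adjusted p = 0.808 with an estimated correlation). For mTORC1 targets the median was 0.76 (camera adjusted p = 0.00426, and adjusted p = 0.554 with an estimated correlation). For light zone genes it was -0.33 and for MHC class II genes -0.31 (camera adjusted p = 0.0271 and adjusted p = 0.0360, and adjusted p = 0.888 for both with an estimated correlation). For 7 myeloid markers it was -3.99 (camera adjusted p = 0.000995, and adjusted p = 0.165 with an estimated correlation). That median rests on fitted values of genes without counts, and the medians within experiments 3 and 4 were -1.30 and -1.27. Without cells marked for both zones 3 of the 5 lists passed.

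The FUCCI reporter intensity, which no comparison of the report uses, was higher in cells that the authors placed in G2M. Its median was 7059 in G2M, 166 in S and 94.5 in G1 cells of experiment 3, and 8941, 246 and 141.5 in experiment 4, in arbitrary units. Forward scatter, a measure of cell size in the sort data, had a median of 103656.5 in G1 cells of KO, 90423 in G1 cells of WT and 89341 in G1 cells of TA. Gmnn, which encodes the replication inhibitor geminin, is missing from the combined table, and in the tables per plate it had 107 CPM in Dec+ and 48.9 CPM in Dec- light zone cells of 12 h. An outlying pair was looked for in 42 genes of the zone comparison over 7 pairs and found in 0. Chance gives about 1 in 20 for genes taken without selection. Many of the 42 were chosen for a low p value and the same sign in all 7 pairs, which favors finding 0. The result therefore does not show that the pairs agree.

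In the zone comparison 34 genes passed in edgeR, and 1 of 100 splits of the 14 sums, the real one, gave as many. The highest of the other splits gave 1 gene, which argues against a random grouping of these 14 sums. Among the 64 splits that part all 7 pairs by harvest, the highest other gave 0 genes. The 7 pairs come from experiments 3 and 4 alone, and 0 and 3 genes passed without each in turn. The splits therefore do not show that the count would recur in another experiment. For gene lists 14 passed with camera, and 5 of 100 splits gave as many or more, with a highest other of 16, so chance cannot be excluded against splits that ignore the pairing by harvest. Those splits mostly leave pairs in 1 group. Among the 64 splits that part all 7 pairs, as the real one does, 2 gave as many lists, the real one and another with 16. That share is under 5%, but the other matched split gave more lists than the real one. Chance is therefore not excluded for the count of lists.

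Of the 52 light zone genes past the threshold at 46 against 12 h, 48 were lower. Random sets of 11 and 13 light zone cells of 12 h, set against the other 12 h cells over 20 draws, gave a median of 8.5 lower genes (0 to 61), and 1 of 20 draws gave 48 or more. The median log2 ratio of all genes had a median of -0.21 over these draws, against -0.30 at 46 h. The draws decide neither way, also since the set of 13 was smaller than the 17 cells of 46 h in experiment 4. Few cells per sum may therefore account for part of the genes. With a mean of 20 CPM over all sums asked of every gene, 76 genes passed, 46 of the 52 among them. That argues against a low mean over all sums as the whole cause. The filter can keep genes with no count at 46 h and left only 6185 genes to adjust over. It therefore does not decide on low counts at 46 h. A change with time stays open and was not tested apart from the number of cells.

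Ccnd2 was higher in KO than in WT dark zone cells, with a log2 ratio of 2.99. Wells of another cell type could carry Ccnd2 reads, but the ratio was 2.40 without wells with few B cell or many T cell genes, which argues against them as the whole cause. A difference by genotype stays open and was not tested apart from one between animals, since no animal is named in the labels.

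Genes of G1/S and mitosis were lower in KO than in WT dark zone cells. Wells of another cell type are argued against, since the G1/S median was -1.80 without them and -1.69 with them. A difference in depth is argued against as well, since with every cell thinned to 100000 reads the share of G1 cells in KO exceeded that in WT by 33.0 points. The G1 share was higher in KO in 4 of 4 plates, as a genotype effect could give. In 1 experiment without named animals, genotype and animal cannot be told apart.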

How the results depend on the processing

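Alternatives chosen only after the data were seen left out wells with few B cell or many T cell genes or cells marked for both zones. The larger sums, all wells and PB wells in the light zone course, phases from list scores, the alternatives for the interaction, those for PB wells and the slope of the dark zone share were also chosen then. For named genes 5030 results were kept under an alternative, 207 lost the call, 17 gained one, 296 moved and 34 reversed. In tested comparisons a kept gene had the same direction and side of the threshold. In untested ones, which have no threshold, its ratio lay within the range over plates. CPM floors cannot change the ratio of a gene. The 264 results under the floor of 5 CPM and 264 under that of 50 CPM were therefore bound to be kept. Leaving out 1 plate can hardly move a pooled ratio out of the range over plates either. Without plates 1, 2, 3 and 4 in turn 200, 208, 202 and 161 results were kept, and these say little about robustness. For lists 401 were kept, 163 lost the call, 1 gained one, 32 moved and 6 reversed. Of the results that answer a comparison 463 were kept, 72 moved, 3 lost the call and 5 reversed. Where not stated otherwise, the cause was not tested.

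On simulated data edgeR recovered 0, 7, 13 and 25 of 50 genes changed 2-fold, 4-fold, 8-fold and 16-fold at the size of the dark zone comparison of 46 with 12 h. It recovered 0, 3, 14 and 20 in the light zone and 14, 22, 27 and 34 between zones. Changes of 2-fold and 4-fold were thus mostly missed in each comparison. Those of 8-fold were mostly missed in both time courses, and those of 16-fold in the light zone course. Depth was not varied in these simulations, so its share in that limit is not known. With size factors of DESeq2, edgeR gave 55 light zone genes at 46 h, 14 at 60 h and 38 between zones. Phases called again from list scores equalled those of the authors in 92.0% of the 965 cells of experiments 1, 3 and 4 and 96.0% of the 373 cells of experiment 5, and in 91.1% and 96.7% of those deep enough to be thinned.

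The DESeq2 test gave 91, 136 and 98 dark zone genes for 30, 46 and 60 against 12 h. It gave 41, 24 and 67 for 46 against 30, 60 against 30 and 60 against 46 h, each where edgeR gave 0. It gave 118, 1054 and 604 light zone genes for 30, 46 and 60 against 12 h, 153 for the interaction and 472 between zones, against 0, 52, 14, 0 and 34 in edgeR. Limma on means of per-cell CPM gave 168 light zone genes at 46 h (48 of the 52 among them), 33 at 60 h and 63 between zones.

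With 1 experiment left out, the lone sum of a group is assumed to vary like those of other groups. The dark zone then gave 0 to 1 gene for 46 against 30 h and for 60 against 30 h. The light zone gave 15 to 42 genes at 46 h, where the 15, 20 and 42 without experiments 1, 3 and 4 shared 14, 1 and 3 genes with the 52, and 0 at 60 h without experiment 1 or 4. Between zones 0 to 3 genes passed. Without the block for experiment, or for experiment and time, 1 gene passed in the light zone at 60 h and 1 between zones. Without a filter on low counts 6 genes passed in the light zone at 60 h. With sums of at least 20 cells 34 passed there and 3 between zones. With all wells of at least 1000 genes 82 light zone genes passed at 46 h, and with PB wells 86. Without cells marked for both zones 34 and 5 light zone genes passed at 46 and 60 h, 76 between zones, and 3 lists instead of 5 for the interaction.

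With an estimated correlation, 0 lists passed in each of the 9 comparisons of times and in the interaction, as with fry, and 7 instead of 14 passed between zones. Without wells with few B cell or many T cell genes 4 lists instead of 7 passed in the dark zone for 60 against 46 h, the Ccnd3 ratio of KO over WT in the light zone was -3.59 instead of -2.14, and the G1/S median there was -1.21 instead of -1.34.

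With means of per-cell CPM, Dec+ over Dec- ratios were 0.022 for Gins1 and -0.068 for Exo1, the median was 1.00 for MYC-dependent growth genes and -0.11 for dissociation stress genes. In PB wells these means gave 0.10 for Xrcc6, -0.28 for Cd38, and medians of -0.63 for G1/S, -0.69 for NF-kB and -0.12 for memory-like genes. Floors of 5 and 50 CPM gave G1/S medians of -0.88 and -0.93 in PB wells. The floor of 5 CPM gave -0.18 for NF-kB there, and the floor of 50 CPM gave 0.79 for mitotic genes of TA over KO in the light zone. With all cells of a genotype, Taf9b in KO was 0.051 and the G1/S median of TA was 0.48, both over WT.

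Without single plates, the Myc ratio of Dec+ over Dec- ran from 1.11 to 2.02 and the G1/S median of TA over WT in the dark zone from 0.51 to 0.76. In the light zone the mitotic median of TA over WT ran from -1.10 to 0.17, the G1/S median from -1.36 to 0.074, and the mitotic median of TA over KO from -0.15 to 1.10. With all wells as denominator, the dark zone share was 76.0% in experiment 3 at 46 h, and 56.2% and 81.2% in experiment 4 at 46 and 60 h, where it was 57.3% at 12 h. The slope of that share with time was then 0.445 points per h instead of 0.562 (exact permutation p = 0.0781 instead of 0.0208). In single experiments it ran from 0.484 to 0.639 points per h (exact permutation p = 0.125 and p = 0.208, with 24 arrangements each, and the cause was not tested). With all wells of at least 1000 genes 50.8% of Dec+ light zone cells of 12 h in experiment 1 were in G1.

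With light zone in place of dark zone cells, ratios of KO over WT were -1.81 for Pls1, -1.32 for Xpnpep3, 2.23 for Taf9b, 0.15 for Snx16, 0.69 for Cyp39a1, 0.40 for Nop2, 0.29 for Bub1, -0.15 for Ell2 and -0.22 for Ssr4. Those of TA over WT were -4.40 for Nanos1, -2.91 for Tgtp2, -1.79 for Pank3, -4.98 for Zfyve1, -4.54 for Oasl2, -0.37 for Brca2, 4.14 for Mterf1b, 0.84 for L3mbtl3, 2.44 for Dock9 and 0.80 for Cd200. They were -1.55 for Ccnd3, -1.59 for Myc, -0.47 for Cdc6, -0.48 for Tacc3, -0.50 for Top2a, -0.67 for Tnfaip3, -0.59 for Ifi213 and -1.62 for Usp18. Medians of TA over WT were -0.40 for G1/S, -0.39 for mitotic, 0.24 for FOXO1 and 0.19 for ribosomal protein genes. Values of TA over KO were -0.026 for Ccne2, -0.88 for Dscc1, -0.88 for Dlgap5 and 1.23 for the G1/S median.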

Other observations

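The values of this part were chosen after the data were seen, and no hypothesis was tested on them.

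In light zone cells interferon response genes had a median log2 ratio of KO over WT of 1.37 (0.07 to 4.15 over plates, 15 of 16 above 0, percentile 100 of random lists) and ribosomal proteins of 0.60 (35 of 36 above 0). Dark zone genes lay at -0.65 (4 of 18 above 0) and hypermutation and repair genes at -0.63 (4 of 17 above 0). In the same contrast 3 expressed T cell markers had a median of 4.84. Without wells with few B cell or many T cell genes the interferon median was 0.97 over 9 genes (-0.0126 to 1.96 over plates), that of ribosomal proteins 0.70, that of dark zone genes -0.58 and that of hypermutation and repair genes -0.48 (percentile 5.55). In TA the interferon median over WT in the light zone was 0.94 (7 of 9 above 0, -0.55 to 1.43 over plates). TA over KO gave a median of 1.38 for hypermutation and repair genes (14 of 16 above 0) and of -0.85 for ribosomal proteins (0 of 36 above 0) in the dark zone. Hypermutation and repair genes were not tested apart from cell cycle phase, the shares of which differed between genotypes.

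The sort intensities went with the zone labels. At 12 h the median of CD83 was 280 in dark and 4732 in light zone cells of experiment 3, and 140 and 4855.5 in experiment 4. The median of CXCR4 was 494 in dark and 143 in light zone cells of experiment 3, and 585 and 116 in experiment 4. In experiment 5 the median of CD86 was 520.5 in KO, 263.5 in WT and 238 in TA dark zone cells, in arbitrary units. Of the 42 dark zone cells of 30 h in experiment 1, the authors placed 9.52% in G1, 40.5% in S and 50% in G2M. Gmnn in the tables per plate had 99.9, 140, 173 and 150 CPM in dark zone cells of experiment 3 at 12, 30, 46 and 60 h, and 111, 173, 240 and 159 CPM in experiment 4.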
